A study of Mus musculus with 4 samples.

How the data were processed

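Whole-genome expression was measured in 4 samples of adult ureter from male FVB/N mice carrying the smooth muscle gamma actin EGFP reporter, at Theiler stage 28. Per the labels' protocols, the samples were not pooled, RNA was extracted with RNeasy columns, amplified in 2 rounds and labelled with biotin. The authors deposited 1 intensity per probe set and array on a linear scale. GCOS, Affymetrix's operating software, is named in the submitters' processing notes, and its version and algorithm are not given in the sources used here. Detection calls and probe-level data were not used here. The mean intensity without the highest and lowest 2% of probe sets was 1500 on every array, so the values had been scaled per array and were used as deposited. No column of another series was present.

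The arrays hold 45101 probe sets. The 64 control probe sets were left out of the tests. Genes were named through the platform's annotation table, in which 34945 of the 45037 tested probe sets have 1 symbol, 932 several and 9160 none. No gene was named from a probe set with several symbols. Gene identifiers of 34741 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names only, and no coordinates are given because no genome build is named for the arrays. In total 18193 genes had a named probe set. A gene's level was that of its probe set with the highest mean, and a gene was above background if any of its probe sets was. Of 9010 genes with 2 or more probe sets, 4625 had probe sets on both sides of that call.

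Levels were log2(intensity + 16). The pseudocount compresses differences among dim probe sets. Each array's background threshold was the 95th percentile of its 83 probe sets for chemosensory receptors, which gave 7.231, 6.98, 7.569 and 7.361 in replicates 1 to 4, and 0 of those probe sets were called above background. A probe set was above background where limma's moderated test of the mean over 4 samples against the arrays' own thresholds, one-sided, had a Benjamini-Hochberg adjusted p under 0.05. Spread was tested on probe sets above background only. The test took the ratio of the variance over 4 samples to limma's trended robust prior variance. Its F test had 3 and 5.44 degrees of freedom. The prior is estimated from the same arrays, so spread that most probe sets share cannot be seen by it. RNA quality differed between arrays. The 3' to 5' signal ratio of Gapdh was 34.35, 36.94, 31.62 and 18.77 in replicates 1 to 4 and that of Actb was 8.231, 19.8, 5.269 and 4.426, which limits probe sets far from the 3' end. After quantile normalization the median level of all probe sets moved by 0.1232, 0.2123, -0.2411 and -0.02722, and that of probe sets above background by under 0.1.

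The 24 gene lists, the tests, the rule for named genes and the alternatives listed here were fixed, except those said to be added, before the data were examined. The lists cover contractile smooth muscle, its channels and receptors, urothelium, regulators of ureter development, fibroblast and matrix, endothelium, macrophage, MHC class II, lymphocyte, mast cell, nerve, adipocyte, mesothelium, kidney, male reproductive tract, skeletal muscle, erythroid, liver, male germ cell, immediate early, interferon, clock, cell cycle and sex-linked genes. In these lists 35 written genes had no probe set named by a single symbol and are not analysed here. Each list's share of genes above background was set against all other named genes with Fisher's exact test, two-sided, adjusted over the lists. For a sample's deviation, the median over the list's genes above background of that sample minus the mean of the other 3 was placed among 10000 random lists of the same size, matched on level in 20 bins. A deviation outside the central 95% is reported as such, and lists of genes drawn at random give 5% of them. Genes of a marker list can vary together, and a list's deviations in the samples are linked. The 5% is therefore no chance rate for the marker lists. In 8 of 60 list and sample pairs the median and the difference of means had opposite signs.

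The rule named Actg2 and the sex-linked genes, up to the first 3 measured genes of every list, the 15 genes with the largest SD among those passing the spread test, of which there were 0, and the 10 genes with the brightest probe sets. Other genes are said to have been chosen after their values were seen. A further 8 lists were added without plan, for striated muscle, liver, exocrine pancreas, lacrimal and salivary gland, prostate, plasma cell, interferon gamma and posterior Hox genes. The last 6 were written after the genes that stood out in some of the samples had been seen. Counts of genes over an array's own threshold and list deviations over all measured genes were also added after the data were examined.

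The alternatives were pseudocounts of 1 and 64, quantile normalization, 3 other backgrounds, a call without a test, other handling of several probe sets per gene, other filters and priors for the spread test, and leaving out each replicate. R 4.3.3 with limma 3.58.1 and matrixStats 1.5.0 was used, with figures drawn in Python 3.11.15 with matplotlib 3.10.9.

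The tests were run on simulated data drawn from the real means and spreads. Of 200 probe sets placed 1 log2 unit above the threshold 134 were called above background, of 200 placed 2 units above it 193 were, and of 21896 with a true mean below it 66 were. For the spread test, the simulation was revised once because its first version recovered none of the shifted probe sets at any shift; that version used the wider variances fitted to all probe sets and shifted 3 sets of 200 together. With variances fitted to probe sets above background, shifting 1 sample by 2, 4 or 8 log2 units recovered 0, 0 and 193 of 200, with 8 false calls among 18397 others at the largest shift. With the wider variances, shifts of 2, 4 and 8 recovered 0, 0 and 73 of 200. A count of 0 in the spread test therefore does not show that samples differed little. For list deviations of 15 genes, 2 of 20 unshifted lists fell outside the central 95%, as did 13 of 20 shifted by 0.5 and 20 of 20 shifted by 1. The simulated genes varied independently, so these counts give no rate for genes that vary together.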

Results

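Gene expression was profiled in the ureter of adult male mice. The mice carried a reporter in which EGFP marks tissue expressing smooth muscle gamma actin (gene symbol Actg2), on the FVB/N strain. The ureter is the muscular tube that carries urine from the kidney to the bladder, and it was dissected between those organs by its green fluorescence. RNA from 4 unpooled samples was amplified in 2 rounds and hybridised to Affymetrix MOE430 arrays, 1 array per sample. All 4 samples belong to 1 group, so no contrast between groups was possible and the question was which genes the adult ureter expressed and how far the samples differed. The samples are called replicates 1 to 4, in an order that carries no meaning. The labels describe each sample as unpooled but do not say that each came from a separate animal. The p-values of the background and spread tests therefore measure only the spread between these samples. Fisher's exact test on the gene lists takes genes as independent units, and its p-values do not measure that spread. The number of arrays limits the precision of every value. Levels are log2(signal + 16), given as mean ± SD with n = 4, and apart from choosing the brightest probe sets, levels of different probe sets were not compared.

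In the adult ureter samples 10578 of 18193 named genes (58.14%) were above background, from 18597 of 45037 probe sets. The count includes genes of other organs that were high in only some samples, such as Pbsn and Pip, named after their values were seen. The genes of contractile smooth muscle, urothelium, connective tissue, vessels, the immediate early response and the circadian clock were above background more often than other genes. Genes of lymphocytes, mast cells, nerve, fat, kidney, male reproductive tract, skeletal muscle, liver and germ cells were above background less often. In all, 15 of the 24 gene lists differed from the other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted), 6 with a higher share and 9 with a lower one. The test asked whether the mean over the 4 samples lay above background, so a gene present in 1 or 2 samples could fail it. Counted sample by sample without a test, 67.4%, 69%, 67.8% and 66.3% of all named genes lay over the array's threshold in replicates 1 to 4. With a background at the median plus 3 median absolute deviations, 6985 genes passed. With a background from the germ cell and liver lists, 1966 genes passed and 1 list differed.

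Contractile smooth muscle genes lay over the background threshold in 18 to 20 of 21 cases in each sample. Of 21 measured genes 19 were above background (90.5%, against 58.1% of the other genes, adjusted p = 0.00696), and 19 when adjusted over the list alone. Actg2, the gene of the reporter, had a level of 11.91 ± 0.96. Acta2, the alpha actin of vascular and visceral muscle, had 14.73 ± 0.70, and Myh11, the smooth muscle myosin heavy chain, had 11.09 ± 0.60. The level of Acta2 is that of a probe set that can match several transcripts, and without such probe sets Acta2 was not above background (adjusted p = 0.179). The 2 genes that did not pass, named after their values were seen, were Myocd at 5.65 ± 0.83 and Casq2 at 7.29 ± 1.55. The list differed between samples, with a median 1.08 log2 units below the other samples in replicate 1 (2 of 19 genes higher) and 1.04 above in replicate 2 (18 of 19 genes higher). Without replicate 2 the median of replicate 1 was -0.615. Actg2 had 11.08 in replicate 1 and 13.30 in replicate 2. Without probe sets that can match several transcripts, the share of contractile genes was 80% of 20 genes and its adjusted p was 0.0662.

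Genes for ion channels and receptors of smooth muscle were above background in 7 of 17 cases, a share not shown to differ from that of other genes (adjusted p = 0.307), and in 7 when adjusted over the list alone. Kcnma1, a large-conductance calcium-activated potassium channel, had a level of 8.94 ± 1.32. Its call was lost without replicate 2 (adjusted p = 0.0703), at the 99th percentile (0.0586) and at the median plus 3 median absolute deviations, where its mean distance from the threshold was -0.358 log2 units, and 1 of its 5 probe sets was above background. Kcnmb1 at 6.19 ± 1.02 and Cacna1c at 6.72 ± 0.65 were not above background.

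Genes of the list for urothelium, the epithelium lining the ureter, lay over the background threshold in 22 or 23 of 24 cases in each sample. The list also holds genes not particular to that lining, such as Epcam and Cdh1. Its share therefore does not tell the ureter's lining from other epithelium. Of 24 measured genes 22 were above background (91.7%, adjusted p = 0.00231), and 22 when adjusted over the list alone. The uroplakins Upk1a, Upk1b and Upk2, membrane proteins of the urothelial plaques, had levels of 10.60 ± 0.89, 15.01 ± 0.56 and 10.02 ± 0.36. The 2 genes that did not pass, named after their values were seen, were high in replicate 3. Upk3a had 14.91 in replicate 3 and 4.55, 6.38 and 7.03 in replicates 1, 2 and 4. Krt20, a keratin of the superficial layer, had 11.69 in replicate 3 and 7.09, 6.31 and 6.07 in the others. The list's median deviation ranged from -0.27 in replicate 4 to 0.24 in replicate 3. In replicate 1 it was -0.04, outside the central 95% of random lists, although the mean of the list was slightly higher there (13.52 against 13.49). That deviation was 0.019 without replicate 2 and 0.0987 without replicate 3.

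**Figure D1:**
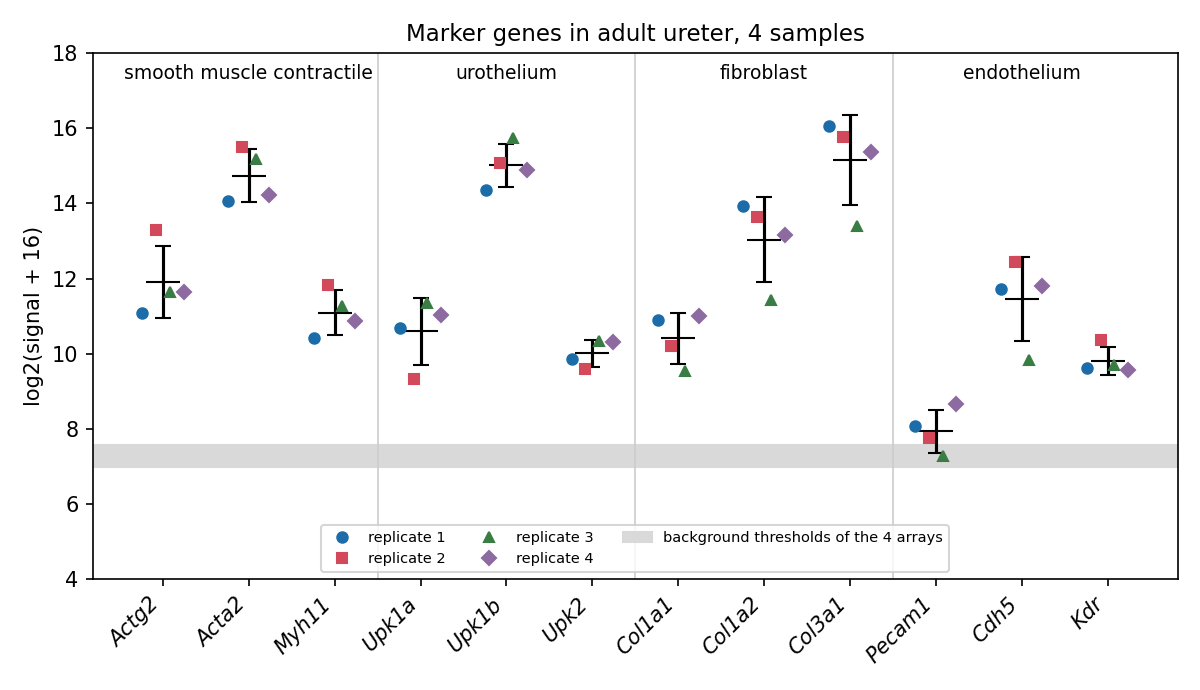
Levels of 12 marker genes as log2(signal + 16), with 1 point per replicate, the mean as a horizontal bar and the SD over 4 samples as the error bar. The grey band spans the background thresholds of the 4 arrays, 6.98 to 7.57, and all genes shown except Pecam1 were above background. Levels compare between replicates of a gene, not between genes.

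Regulators of ureter development were above background in 15 of 21 cases (71.4%), a share not shown to differ from that of other genes (adjusted p = 0.361), and in 15 when adjusted over the list alone. Tshz3 and Tshz2, zinc finger factors, had levels of 9.45 ± 0.87 and 13.48 ± 0.35. Tbx18, which patterns the embryonic ureteric mesenchyme, was not above background at 6.75 ± 2.01, with 9.48 in replicate 3 and 5.17 to 7.03 in the others. The list's median deviation stayed within the central 95% of random lists in every sample.

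Connective tissue and vessel genes were expressed in the ureter and were low in replicate 3. Of 19 fibroblast and extracellular matrix genes 18 were above background (94.7%, adjusted p = 0.00233), and 18 when adjusted over the list alone. The collagen genes Col1a1, Col1a2 and Col3a1 had levels of 10.41 ± 0.68, 13.04 ± 1.12 and 15.15 ± 1.20. The exception, named after its values were seen, was Pi16 at 8.27 ± 2.47. Of 16 endothelial genes 15 were above background (93.8%, adjusted p = 0.00803), and 15 when adjusted over the list alone. Cdh5, the cadherin of endothelial junctions, had 11.45 ± 1.12, and Kdr, a receptor for VEGF, had 9.81 ± 0.37, while Pecam1 at 7.94 ± 0.58 did not pass, though it did without replicate 3 (adjusted p = 0.0171). In replicate 3 none of the 18 fibroblast genes and none of the 15 endothelial genes was higher than in the other samples, with medians of -2.03 and -1.74. In replicate 2 the medians were 1.02 and 1.22, and without replicate 3 they were 0.179 and 0.656. Replicate 3 was also the sample in which all 14 skeletal muscle genes lay over the background threshold. The fibroblast median of replicate 4, 0.37 with all samples, was -0.545 without replicate 3.

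Macrophage genes were above background, while no lymphocyte or mast cell gene passed the test. Of 16 macrophage and myeloid genes 11 were above background (adjusted p = 0.504), and 11 when adjusted over the list alone. They included Csf1r, the receptor for colony stimulating factor 1, at 12.00 ± 0.38, Cd68 at 9.18 ± 0.40 and Adgre1 at 8.94 ± 0.58. Of 7 MHC class II genes 4 passed (adjusted p = 1), namely H2-Aa at 12.35 ± 1.05, H2-Ab1 at 10.33 ± 0.98, H2-Eb1 at 10.22 ± 1.79 and, named after its values were seen, Cd74 at 10.96 ± 1.07. The count was also 4 when adjusted over the list alone. H2-Ab1 was not above background without probe sets that can match several transcripts (-0.281), and H2-Aa, which has only such probe sets, could not be measured that way. None of 13 lymphocyte genes passed (adjusted p = 0.000289) and none of 8 mast cell genes did (adjusted p = 0.00282, and 0.0503 at the median plus 3 median absolute deviations), with 0 and 0 when adjusted over the list alone. Counted sample by sample, 7 of the 13 lymphocyte genes lay over the array's threshold in replicate 2, against 1, 3 and 5 in replicates 1, 3 and 4. In each sample this was a smaller share than among all named genes. Cd3g had 10.41 in replicate 2 and 7.18 to 7.93 elsewhere.

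The medians of 3 immune lists lay above the other samples in replicate 2. The MHC class II median was 1.93 log2 units above the mean of the other 3 samples there, the interferon response median 1.27 and the macrophage median 0.60, with all 4, 9 and 11 genes above background higher than that mean. Cd68 was nevertheless highest in replicate 1 at 9.70, and so was Csf1r at 12.35 by its brightest probe set. The other Csf1r probe sets, also above background, were highest in replicate 2 (10.41) and in replicate 4 (8.585). Of the 8 mast cell genes 0 were higher in replicate 2. That array also had the highest 3' to 5' ratios of Gapdh and Actb (36.94 and 19.8) and the highest Svs4 level (14.80), and whether the immune medians depend on either was not tested. The interferon list had 9 of 12 genes above background (adjusted p = 0.457), and 9 when adjusted over the list alone. Ifit1, an interferon-induced antiviral gene, had 11.63 in replicate 2 and 8.57 to 10.19 in the others. In replicate 3 the macrophage and interferon medians were -0.69 and -0.69, and in replicate 4 the MHC class II median was -1.02. Without replicate 2 the interferon median of replicate 3 was -0.287 and the MHC class II median of replicate 4 was -0.421, and without replicate 1 the former was -1.05.

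Genes of nerve and fat were less often above background than other genes. Of 13 nerve and Schwann cell genes 3 passed (adjusted p = 0.0339), and 3 when adjusted over the list alone. These were Mbp, a myelin protein gene, at 12.51 ± 0.48 and, named after their values were seen, Pmp22 and Gfra3. S100b at 7.48 ± 1.49 and Sox10 at 7.71 ± 1.26 did not pass, though Sox10 did without replicate 2 (adjusted p = 0.0297). Of 10 adipocyte genes 2 passed (adjusted p = 0.0339), Scd1 and Lpl, also named after their values were seen, and 2 when adjusted over the list alone. Without replicate 4 the adjusted p of the nerve list was 0.153 and that of the adipocyte list 0.179, and without replicate 2 that of the adipocyte list was 0.17. The adipocyte list also lost its call with a pseudocount of 64 (0.168), a background at the 99th percentile (0.0823) or at the median plus 3 median absolute deviations (0.161), and a call without a test (0.167). The nerve list lost its call at the median plus 3 median absolute deviations (0.226). Fabp4, a fatty acid binding protein gene of fat cells, had 14.93 in replicate 3 and 7.06 to 8.33 in the others, and Adipoq was not above background (5.95 ± 1.34).

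Of 7 mesothelium genes 3 were above background (adjusted p = 0.504), and 4 when adjusted over the list alone. Msln and Upk3b moved apart between samples. Msln, the mesothelin gene, was lowest in replicate 3 at 7.31 against 11.14 to 13.60, while Upk3b was highest there at 14.34 against 10.44 to 11.73. The third gene, Gpm6a, named after its values were seen, had 12.15 ± 1.48. Of 5 erythroid genes 2 passed (adjusted p = 0.684), and 2 when adjusted over the list alone, Hbb-b2 at 8.80 ± 0.76 and Alas2 at 8.94 ± 0.76. Hba-a1 did not pass (5.62 ± 1.07).

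Genes of other organs lay over the background threshold in more cases in some samples than in others. All 14 skeletal muscle genes lay over the background threshold in replicate 3, against 3, 4 and 5 in replicates 1, 2 and 4. Myh4, a fast myosin heavy chain, had 16.39 in replicate 3 and 4.14 to 4.52 in the others. Acta1, the skeletal alpha actin, had 14.90 against 4.35 to 6.88, and Ckm, muscle creatine kinase, had 13.03 against 5.64 to 7.26. The list median was 6.28 log2 units above the other samples in replicate 3. All 11 liver genes lay over the threshold in replicates 1 and 3, against 3 and 1 in replicates 2 and 4. Alb, the albumin gene, had 14.58 in replicate 1, 11.84 in replicate 3, 6.91 in replicate 2 and 7.88 in replicate 4. The liver medians were 3.19 and 1.38 above the other samples in replicates 1 and 3. Of 12 male reproductive tract genes, 10 and 9 lay over the threshold in replicates 1 and 2, against 4 and 3 in replicates 3 and 4. Svs4, a seminal vesicle secretory protein gene, had 14.80 in replicate 2, 11.96 in replicate 1, and 6.55 and 6.63 in replicates 3 and 4. These medians over all measured genes and these counts per sample were added after the data were examined.

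By the test of the mean, 2 of 14 skeletal muscle genes (adjusted p = 0.00398), 0 of 11 liver genes (adjusted p = 0.00055) and 1 of 12 male reproductive genes (adjusted p = 0.00231) were above background. The counts were 1, 0 and 0 when adjusted over the list alone. The genes that passed, named after their values were seen, were Tnni2, Tcap and Pbsn. Without replicate 4 the liver list no longer differed (adjusted p = 0.121). Alb, with an adjusted p of 0.0502 in all samples, passed without replicate 2 (0.0306) and without replicate 4 (0.0381), and Apoa2 passed without replicate 4 (0.0166). Kidney genes were above background in 2 of 16 cases (adjusted p = 0.00231), and in 2 when adjusted over the list alone. These were Aqp1, a water channel also found in vessels, and Kap, both named after their values were seen. Umod at 5.32 ± 0.66, Slc12a1 at 6.35 ± 0.36 and Slc12a3 at 5.08 ± 0.54, transporters and a secreted protein of the nephron, were not above background. None of 12 male germ cell genes passed (adjusted p = 0.000345), and 0 when adjusted over the list alone.

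**Figure D2:**
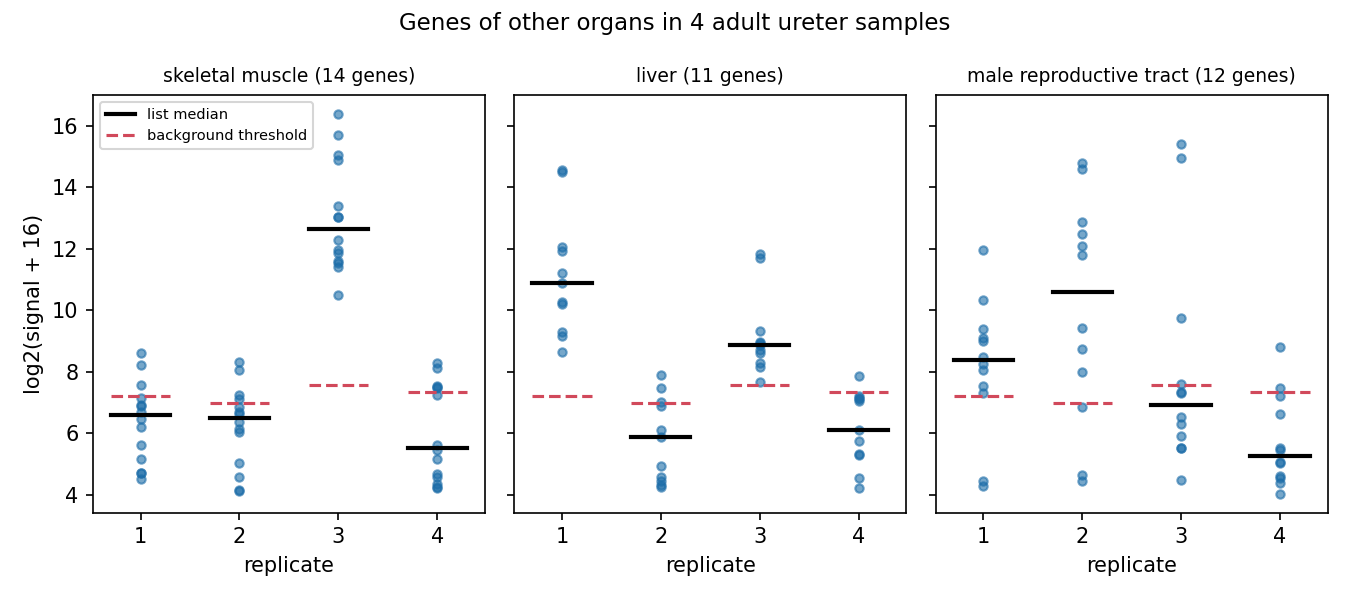
Levels of the measured genes of the skeletal muscle, liver and male reproductive tract lists as log2(signal + 16), with 1 point per gene and replicate, the list median as a black bar and the array's background threshold as a dashed line. The skeletal muscle median was 12.66 in replicate 3 and at most 6.59 in the others, and the liver median was 10.89 and 8.89 in replicates 1 and 3 and at most 6.12 in the others.

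Stress, clock and proliferation genes were expressed. Of 18 immediate early and heat shock genes 16 were above background (adjusted p = 0.015), and 16 when adjusted over the list alone. Fos, an early response transcription factor, had 13.46 ± 1.31, with 11.57 in replicate 4 and 13.60 to 14.37 in the others, and Jun had 11.75 ± 0.38. Fosb and, named after its values were seen, Egr2 did not pass. Of 14 circadian clock genes 13 passed (adjusted p = 0.0212), and 13 when adjusted over the list alone, with Clock at 11.95 ± 0.14 and Arntl at 9.74 ± 0.75. Their median was -0.67 in replicate 3 and 0.52 in replicate 4. Of 11 cell cycle genes 8 passed (adjusted p = 0.457), and 8 when adjusted over the list alone. Mki67, a proliferation marker, had 9.46 in replicate 1 and 10.92 to 11.65 in the others, and Top2a had 12.73 in replicate 2. In replicate 1 the cell cycle median was -1.34 with 0 of 8 genes higher, and in replicate 2 it was 0.96 with 8 of 8 higher.

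The labels give all 4 samples as male. The Y-linked genes Eif2s3y at 12.60 ± 0.37, Kdm5d at 9.22 ± 0.57 and Uty at 8.70 ± 0.87 were above background. At the median plus 3 median absolute deviations Kdm5d (-0.0824) and Uty (-0.595) lost their calls, and at the 99th percentile Uty did (adjusted p = 0.0646). Xist, the RNA of the inactive X chromosome, had 1 of 3 probe sets above background, at 8.40 ± 0.90. That probe set can match several transcripts, and without such probe sets Xist lay below the threshold (-2.64). Its call was also lost without replicate 1 (adjusted p = 0.0933), without replicate 4 (0.11) and at both other backgrounds named here. The sex-linked list had 4 of 4 genes above background (adjusted p = 0.217), and 4 when adjusted over the list alone. The 10 genes with the brightest probe sets, in no order of rank, were Gsn, Rps3a1, Rps29, Akr1a1, Rpl13a, Tpt1, Eef1a1, Hmgn1, Rps28 and Hspa8.

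**Figure D3:**
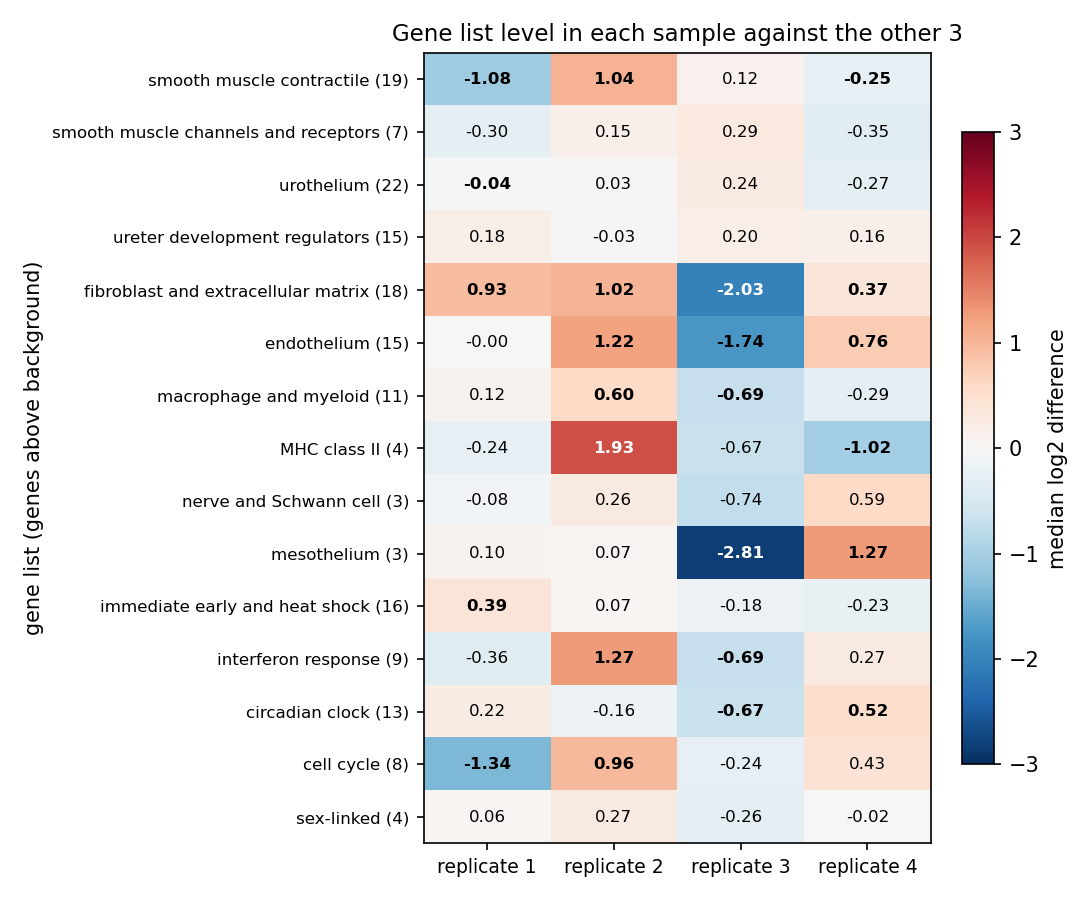
Median log2 difference of each gene list in 1 replicate from the mean of the other 3, over the list's genes above background, whose number stands in parentheses. Bold values lie outside the central 95% of 10000 random lists matched on level. The lowest value is -2.81, for mesothelium in replicate 3, and the highest is 1.93, for MHC class II in replicate 2.

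Across probe sets above background, replicate 3 stood apart from the rest. Its Pearson correlations with the other samples, taken across probe sets that are not independent replicates, were 0.855 to 0.886, against 0.917 to 0.933 among the other pairs. Between 13.6% and 27% of probe sets differed over 2-fold between a pair. Among all tested probe sets, 349 lay over the array's threshold in replicate 3 and at least 8-fold higher than in every other sample, against 42, 36 and 55 in replicates 1, 2 and 4. In replicates 1 to 4, 70, 119, 102 and 36 were at least 8-fold lower than in every other sample while over the threshold in those 3. The deviation of a list in 1 sample has no replicate check and carries no p-value. Of 60 list and sample pairs, 24 lay outside the central 95% of random lists.

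No probe set passed the test for more spread than others of its level. Among 18597 probe sets tested with limma's trended prior and an F test, 0 passed after Benjamini-Hochberg adjustment and 1156 (6.22%) had an unadjusted p under 0.05. The smallest adjusted p was 0.05003 and was shared by 10 probe sets, of which 7 have 1 symbol, for the genes, named after their values were seen, Prol1, 2310057J18Rik, Pip, Car6, Smr2 and Olfm4. Prol1 had the smallest unadjusted p, with levels of 8.02 in replicate 1 and 15.99, 16.89 and 15.56 in the others. No gene could therefore be named by its spread, and no list could be tested among high-spread genes. The count was 6 with a pseudocount of 1, 10 with a background at the 99th percentile, 5 without replicate 2 and 7 without replicate 3. Only probe sets above background were tested, and a high spread counts against that call, so the filter removes part of what was sought. Svs4 (SD 4.09) and Alb (SD 3.56) were left out, although their means lay 2.70 and 3.02 log2 units over the threshold. With no filter on dim probe sets, 0 of 45037 passed.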

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

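Of the tests in this part, only the count on the second striated muscle list and the test of a single liver-like source were set down before their results were seen, and all others, with the level-matched comparison of that count, were chosen afterwards. No biological explanation was tested, because the design has 1 group. Of 112 values examined for a sample far from the others, 6 stood out, and chance gives about 5.6 at 1 in 20. Of these, 4 concern replicate 3.

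Skeletal muscle genes stood out in replicate 3. The gap of the skeletal muscle list's median to the nearest sample was 6.07 log2 units, and that of Myh4, a myosin of fast muscle fibres, was 11.9. A second list of striated muscle genes had 20 of 24 measured genes highest in replicate 3, and in the other samples 6, 10 and 7 of the 24 lay over the background threshold. Other genes of the same level were highest in replicate 3 more often than the 25% of an even split: those matched on their mean in replicates 1, 2 and 4 gave 42.2%, and those matched on all 4 gave 40.1%. The highest count among 10000 random lists was 19 and 18 with these matches. After quantile normalization 19 of the 24 were highest there, against 24.7% and 23.3% of matched genes and at most 16 and 13. Less degraded RNA in replicate 3 was argued against, because replicate 4 had lower 3' to 5' ratios while its muscle median of 5.544 lay below its threshold of 7.361, and so was array scaling, because the median difference stayed at 6.18 after quantile normalization. RNA of striated muscle in replicate 3 is a candidate explanation, and how it got there, in the dissection or later, stays open.

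Liver genes stood out in replicates 1 and 3. In a second liver list 16 of 21 genes (76.2%) were higher in both of these replicates than in both others. This was more than an even ordering of the samples would give, and no share of level-matched genes was computed. It was short of the 80% that liver RNA was required to give, a bound set afterwards. In replicates 2 and 4, 9 and 8 of the 21 genes lay over the threshold. After quantile normalization the liver list's median difference from replicates 2 and 4 was 4.44 in replicate 1, which argues against array scaling there. In replicate 3 it was 2.86 (SD over genes 1.54), short of the 3 log2 units set afterwards as the bound against scaling. As deposited it was 3.25, so that normalization left most of it. All 11 of 11 genes were higher after it, the lowest by 0.989, and these values argue against scaling alone for this list in replicate 3. A single liver-like source in different amounts would give genes with no other source a constant ratio between replicates 1 and 3. In the second list the log2 ratio had an SD of 0.934, against a median of 0.927 for matched random genes (percentile 51.3). The bound set down beforehand for rejecting such a source, an SD at or above that median, was met, but the reading of the test was changed after the value was seen: matched genes that mostly do not change show the same noise as genes at a constant ratio, and the excess of the SD was small beside its spread, so the test can neither support nor exclude 1 source. Some genes of the second list were also bright in replicates 2 and 4, such as Apoc1 (10.35 and 10.39) and Arg1 (10.91 and 11.66). Such genes can widen the SD whether or not there was 1 source. Liver RNA may have entered these samples, and the test leaves it open.

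Seminal vesicle genes stood out in replicates 2 and 1. For 6 genes the median difference from replicates 3 and 4 after quantile normalization was 7.32 in replicate 2 and 3.48 in replicate 1, which argues against array scaling in both. Of these genes Svs4 reached 14.80 in replicate 2 and 11.96 in replicate 1. The SD of their log2 ratio was 0.647, against a median of 0.564 for matched random genes (percentile 63.6). This met the rejection bound for 1 source as first written, and the same later change of reading applies, so 1 source of seminal vesicle RNA cannot be told apart from several with 6 genes. RNA of male accessory glands, which lie near the bladder, may have entered these samples, in the dissection or later, untested beyond these values.

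The median of the nerve and Schwann cell list was 8.17 in replicate 3, 1.08 log2 units above the nearest sample. Set against the mean of the other samples, all 13 genes had a median of 0.40 there, at percentile 70.68 of random lists, and the 3 above background had -0.74, with 1 higher and Mbp lowest there at 11.96. The median of the interferon response list was 10.73 in replicate 2, 1.8 above the nearest sample. Fabp4 was 6.6 log2 units higher in replicate 3 than in the nearest sample. Gsn was -0.508 log2 units from the nearest sample in replicate 4, at 16.22. All 10 genes with the brightest probe sets were lowest in replicate 4. The highest signal on that array was 77936.14, against 108593.6 to 122593 on the others, so the Gsn value is not particular to that gene.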

How the results depend on the processing

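No paired analysis was possible because there is 1 group. Tests of the mean were limited by signal over background, and 4625 genes had probe sets on both sides of the call. Background set the counts most. Against 18597 probe sets and 10578 genes, a background at the median plus 3 median absolute deviations gave 10439 and 6985, and one from the germ cell and liver lists gave 2782 and 1966, all of these genes shared with the first count. With that last background 1 list differed, in place of 15, and the share of endothelial genes fell to 0%, below that of other genes. Its liver genes were high in replicates 1 and 3, which raises the threshold by construction. Other settings kept these counts within 1.5 times. Leaving out 1 replicate gave 17825 to 18395 probe sets, 10309 to 10590 genes and 12 to 15 lists. The 12 came without replicate 4, when the nerve, adipocyte and liver lists lost their calls. At the median plus 3 median absolute deviations the nerve, adipocyte and mast cell lists lost theirs, and so did Xist, Kdm5d, Uty, Kcnma1, Upk2, Tshz3, Col1a1, Kdr, Cd68, Adgre1, H2-Ab1, H2-Eb1, Msln, Hbb-b2, Alas2, Ifit1, Ifit2, Ifit3, Arntl and Ccnb2. At the 99th percentile Xist, Uty, Kcnma1 and Ifit2 did, and Ifit2 also did without replicate 1 or without replicate 2.

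The spread test gave 0 calls as planned, 6 with a pseudocount of 1 and 10 with a background at the 99th percentile. Leaving out 1 replicate gave 0 to 7, with 5 without replicate 2 and 7 without replicate 3. The other settings gave 0, and the cause was not tested. The calls were too few under every setting to test a list among high-spread genes, and its count of 0, and 0 to 0 with a replicate left out, shows nothing.

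List deviations outside the central 95% numbered 24 of 60, 18 to 28 with a replicate left out, and 42 over all measured genes, a setting added after the data were examined that takes in more lists. Among medians outside the central 95%, those that changed sign with a replicate left out were those of contractile smooth muscle in replicate 4 (-0.685 to 0.187 with a replicate left out, the latter without replicate 2), urothelium in replicate 1 (-0.0653 to 0.0987, with 0.019 without replicate 2 and 0.0987 without replicate 3) and fibroblast genes in replicate 4 (-0.545 to 0.734, the former without replicate 3). With those inside the central 95% counted, 27 of 177 such values had the other sign, among them nerve genes in replicate 4 (-0.178 without replicate 3) and mesothelium in replicate 2 (-0.463 without replicate 3). In each the comparison then rests on 2 other samples. Among list shares 263 of 288 values kept their side of the adjusted p threshold, 24 lost the call and 1 reversed. Direction was compared only where a share differed from the other genes in at least 1 of the 2 settings. Among deviations 432 of 473 moved by less than the spread and 37 moved by more. Among named genes 919 of 992 kept their call, 68 lost it and 5 gained it.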

Other observations

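The genes and lists in this part were chosen after values were seen. A list's deviation in a sample that prompted the list is therefore no separate support. Most secretory genes of lacrimal and salivary glands were higher in replicates 2, 3 and 4 than in replicate 1. Of 14 measured genes 5 lay over the background threshold in replicate 1, against 11, 11 and 10 in the others, and the list's median deviation in replicate 1 was -4.90 log2 units. Pip, the prolactin-induced protein gene, had 5.30 in replicate 1 and 13.33, 16.16 and 13.45 in replicates 2, 3 and 4. Car6, a secreted carbonic anhydrase, had 5.95 against 13.29, 15.28 and 15.35. Both had been seen to be low in replicate 1 before the list was written. Amy1, Lcn11, Bpifa2 and Dmbt1 were not lowest in replicate 1, and of these only Amy1 was above background. Amy1 had 9.565 there and 9.075 to 10.47 in the others, and Lcn11 was highest there at 6.66. The plasma cell list had a median deviation of -0.08 in replicate 1, with a mean of 9.03 there against 10.28 in the others. Igha, the immunoglobulin A heavy chain, had 4.98 there and 12.03, 11.06 and 9.63 in the others, and Jchain and Pou2af1 were also lowest there, while Tnfrsf17 and Sdc1 were highest there and Ighm, Mzb1 and Xbp1 were neither. Exocrine pancreas genes went the other way, with a median deviation of 1.46 in replicate 1. Counted by any probe set, 13 of 13 lay over the threshold there, against 2, 4 and 3 in the others. The list median there was 7.859, near the threshold of 7.231. By the test of the mean only Cela3b was above background, and it was lowest in replicate 1 at 7.859. Cela1 and Rnase1 were highest in replicate 3, at 12.4 and 8.231, and the remaining genes in replicate 1.

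Genes of the prostate were highest in replicate 3, with a median deviation of 4.81 and 9 of 9 genes higher than in the other samples. Over the 3 genes above background the median deviation was 0.71, at percentile 95.33 of random lists. Msmb, a secreted prostate protein gene, had 16.27 in replicate 3 and 4.76 to 7.43 in the others, and Pbsn, the probasin gene, had 15.41 and 8.80 to 9.42. The list shares 2 genes with the male reproductive list. Posterior Hox genes gave a more even picture, with median deviations from -0.23 to 0.19 over all 16 measured genes. Over the 7 genes above background they ran from -0.42 to 0.18. Hoxa9 at 14.70 ± 0.13, Hoxa10 at 12.43 ± 0.29 and Hoxd13 at 14.64 ± 0.56 (SD, n = 4) were above background, while Hoxb13, which the prostate list also holds, had 10.70 in replicate 3 and 4.30 to 4.61 in the others.

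Genes induced by interferon gamma and used in antigen processing had a median deviation of 1.27 in replicate 2, with 14 of 15 genes higher than the mean of the other samples. B2m was highest in replicate 3, Irf1 in replicate 4 and Socs1 in replicate 1. Igtp had 13.10 in replicate 2 and 10.64 to 11.62 in the others, and Psmb8, an immunoproteasome subunit, had 12.41 and 10.36 to 10.92. Among single genes, Cxcl9 had 11.07 in replicate 2 and 4.38 to 6.88 elsewhere, and Ido1 had 11.62 and 5.995 to 7.65.

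Genes of the spread test's alternative settings were in part the gland genes. With a pseudocount of 1 the 6 calls included Car6, Pip, Prol1 and Smr2, and 2310057J18Rik, Prol1 and Smr2 were called under all 4 settings that gave calls.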
